A study of Vitis vinifera with 204 samples.

How the data were processed

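Poly(A)-selected RNA of grapevine buds was sequenced as single reads of 75 bases, per the labels' protocols, in 204 libraries of 2 cultivars. The values used are the authors' deposited count table: whole numbers for 20000 row identifiers in 204 columns, not scaled to a common total, and named as read counts by the authors. FastQC, MultiQC, Trimmomatic, STAR and featureCounts are named in the submitters' processing notes. Their versions and settings, the genome build and the annotation are not given in the sources used here. Each column name equalled 1 sample's title, and 0 columns were without a sample. Rows that name no feature numbered 0.

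Whether the deposited values are counts of reads per grapevine gene could not be established. The identifiers are a gapless numbered sequence that matches 0 of 29591 genes in the reference list (assembly ASM3070453v1, used for names only), and the values showed no row-specific level, as the results describe. The tests below treat the values as counts, as named by the authors, and their outcome describes the deposited table. They do not show whether gene expression in the buds changed.

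Samples were grouped by cultivar, date and hour from their titles. Weather is shared by the vines of a time point, so counts of the 3 vines were added per time point and days were the replicates for hour and period. Added counts weigh each vine by its total, so a deep library can dominate a sum (525055, 4573384 and 14405924 counts in the 3 Riesling libraries of January 16 at 14:00). Each hour comparison used 44 such sums (22 time points per cultivar) with a block for each day of each cultivar and 20 residual degrees of freedom. Each period comparison used 34 sums at 14:00 (26 residual degrees of freedom), with January 23 left out. In each of these fits both cultivars were together and shared a single estimate of each row's spread. The sums of the 2 cultivars come from the same days, and comparisons over both cultivars had no term for a shared day, so these degrees of freedom count each day 2 times and may overstate the replication. For the 4 comparisons over both cultivars the counts of the cultivars were therefore also added per time point, which left 22 sums with 10 residual degrees of freedom for hours (8 days) and 17 sums with 13 for periods (17 days). The cultivar comparison used all 68 sums with a block for time point (33 residual degrees of freedom). The day course used single libraries with vines as replicates. The labels say that the vines of a time point were separate and do not say whether the same vines were used again at other times.

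Tests were run in edgeR 4.0.16 (quasi-likelihood F test, trimmed-mean normalization, filterByExpr, R 4.3.3), with Benjamini-Hochberg adjustment over the 20000 rows and a threshold of 0.05 on the adjusted p. The filter removed 0 rows, so the alternative without it is the same fit. DESeq2 1.42.0 was an alternative. The other alternatives were DESeq2's size factors, leaving out each replicate number, leaving out each day, single libraries as replicates with and without the replicate number as a block, wider windows for the cycles, other limits and comparators for the constant period, and, for cultivars, sums over all time points per replicate number and the 14:00 samples alone. Leaving out the 6 libraries under 1000000 counts was added after the totals were seen, and adding the cultivars' counts after the results were seen. The tests of depth, row distribution, spread and column totals were also chosen after the values were seen. All other choices for the comparisons of hours, periods, days and cultivars, the gene lists and the rule for naming genes were fixed before the data were examined. That rule was to name the 8 highest and 8 lowest called genes per main comparison, with descriptive names and the same direction on every day, together with members of the clock and CBF lists. No row was called or could be named, so it selected none. The planned camera tests of gene lists were not run because 0 of the 23 lists had a member.

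The row distribution of each library was compared with a negative binomial distribution of size 2 and with a rounded gamma distribution of shape 2, by the largest distance between cumulative curves and 199 simulated draws per library (scipy 1.17.1, numpy 2.4.6). CPM were computed from the column totals with a pseudocount of 1. Splits of the samples were 21 per result, the real one included. For the cultivars, the other splits kept the dispersion trend of the real labels. The test code was tested on simulated data with 200 changed rows. Column totals from 525055 to 38336259 counts set the depth. Wherever the values are counts, the precision they give covers counting error only.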

Results

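The deposited table held no expression difference between hours, periods, days or cultivars that passed the main test, and its rows could not be tied to grapevine genes. It covered winter buds of 2 cultivars of Vitis vinifera, the white-berried Riesling and the red-berried Cabernet Franc, taken from a commercial vineyard in January. Each cultivar was sampled at 34 time points between January 14 and January 31, with 3 samples of 3 pooled buds at each time point, each from a separate vine. This gave 68 groups of 3 libraries, 204 libraries in all. Temperatures moved above and below freezing in 2 diurnal cycles. These cycles are taken here as the whole days January 14 to 17 (first cycle) and January 24 to 27 (second cycle). Each was sampled in the light at 14:00 and in the dark at 06:00 and 18:00. Between them lay a period of constant sub-zero temperature, taken as January 18 to 22 and sampled at 14:00. The 06:00 sampling of January 18 was counted with it in the totals, and the main tests of hour and period left that sampling out. A cycle is given as 84 hours and the constant period as 96 hours, so that sampling may instead close the first cycle. The wider windows for the cycles include it there, and also take in January 23. The labels gave no temperature regime for January 23 or for January 28 to 31.

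The rows of the table carried 20000 identifiers that ran from ENSG00000000001 to ENSG00000020000 with every one of the 19999 steps equal to 1. The ENSG prefix is the one Ensembl uses for human genes, whereas the samples were grapevine. Of the 20000 identifiers, 0 matched any of the 29591 genes of the grapevine reference list by gene number, locus tag, symbol, synonym or accession. None of the rows could therefore be assigned to a gene, a chromosome position or a pathway. The 23 gene lists fixed beforehand, among them the circadian clock, the CBF/DREB1 cold regulators, dehydrins, galactinol and raffinose synthases and dormancy-associated genes, had no member in the table and were not tested.

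Column totals ranged from 525055 to 38336259 counts. Cabernet Franc libraries had a mean total of 15672990 ± 5492270 (SD, n = 102) and Riesling libraries one of 12252123 ± 7790571 (SD, n = 102). Of the 6 libraries under 1000000 counts, 5 were Riesling replicate 1 on January 14 to 16 and 1 was Cabernet Franc replicate 3 at 14:00 on January 17 (726919 counts). Riesling replicate 1 had a median of 946938 over its 8 libraries of January 14 to 16, against 16329898 over its 17 libraries of January 17 to 25. Riesling replicate 2 had a median of 4573384 over 17 libraries up to January 22 and 14965370 over 17 libraries from January 23 on. Within Riesling the first cycle had a mean of 9078849 ± 7636337 (SD, n = 33) and the constant cold period 16643638 ± 10823297 (SD, n = 18), the latter with the 06:00 sampling of January 18. The corresponding Cabernet Franc values were 14572180 ± 5333806 (SD, n = 33) and 14641782 ± 5515051 (SD, n = 18).

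**Figure D1:**
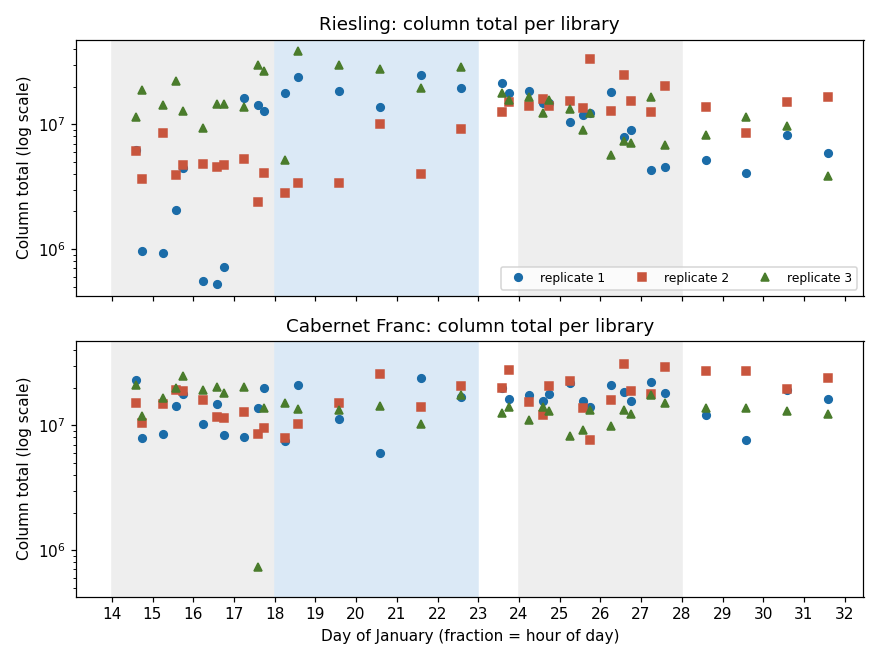
Column total of each library (log axis, counts) against day of January, with one point per library, Riesling above and Cabernet Franc below, and replicate numbers as symbols. Grey bands mark the 2 diurnal cycles and the blue band the constant sub-zero period, all drawn by whole days. Of the 6 points under 1000000 counts, 5 are Riesling replicate 1 on January 14 to 16 and 1 is Cabernet Franc replicate 3 on January 17.

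The rows differed little in level. The mean count of a row over the 204 libraries ranged from 546 to 881 with a median of 697, a 1.61-fold range from the lowest row to the highest. In counts scaled to the column total (CPM) the row means lay between 41.1 and 60.3, around a median of 49.9. The SD of a row over the 204 libraries had a median of 35.1 CPM. Of the 4080000 values, 69 were 0, and 19931 rows had no 0 in any library. The top 200 rows of a library, 1 in 100, held between 3.74% and 4.03% of its counts. The variance of the row means on the log2 scale was 0.995 times the variance that 20000 interchangeable rows would give. The coefficient of variation of a row over libraries had a median of 70.3%, while Poisson counting alone gives 3.80% at the median library's mean.

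Libraries of one cultivar and time point were no more alike than other libraries. Pearson's r of log2(CPM + 1) across rows averaged 0.00018 over the 204 pairs of libraries from the same group (range −0.0215 to 0.0180). It averaged −3e-05 over the other 20502 pairs (range −0.0258 to 0.0265). The spread of r over those other pairs was 0.00709 (SD), and unrelated rows would give 0.00707. These correlations are across rows, which are not independent replicates of the samples. No pair of libraries held identical values. The first principal component carried 0.596% of the variance, where equal components would carry 0.493% each.

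**Figure D2:**
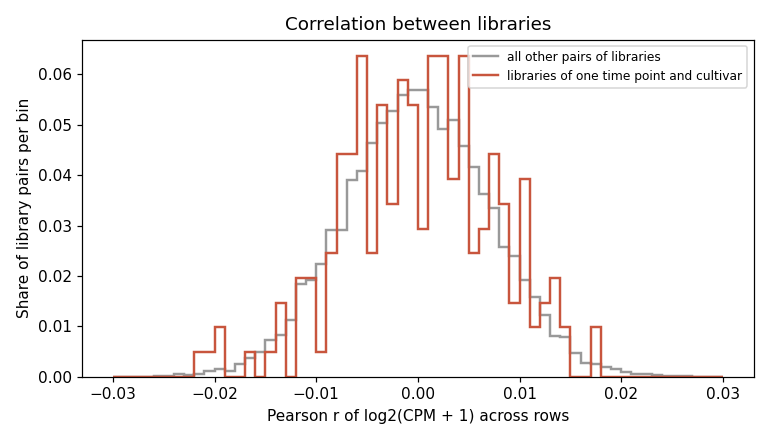
Share of library pairs (vertical axis) by Pearson's r of log2(CPM + 1) across rows (horizontal axis), for the 204 pairs of one cultivar and time point and for the other 20502 pairs. Both distributions centre on 0 and lie between −0.0258 and 0.0265.

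The first comparison addressed the effect of the hour of sampling in the freeze-thaw cycles, with counts of the 3 vines added per time point and days as replicates. In Riesling 0 of 20000 rows differed between 14:00 and the mean of 06:00 and 18:00 (edgeR quasi-likelihood test, smallest Benjamini-Hochberg adjusted p = 0.223). In Cabernet Franc the count was also 0 (edgeR, smallest adjusted p = 0.999). The log2 fold changes of the central 95% of rows lay between −0.63 and 0.62 in Riesling and between −0.57 and 0.56 in Cabernet Franc. A row's fold change had a median standard error of 0.303 and 0.302, alike by construction because the cultivars shared a single estimate of the spread. If their own spreads differ, p-values are too small in the more variable cultivar and too large in the other, which was not tested. The constant-cold comparison below has the same limit. At an unadjusted p under 0.05 there were 1215 rows (6.08%) in Riesling and 757 rows (3.79%) in Cabernet Franc, where chance gives 5%. With single libraries in place of sums the counts were 826 (4.13%) and 862 (4.31%), so the difference between the cultivars in these shares was not kept. In sums, Riesling had the wider fold changes and the larger share at an almost equal standard error, as a larger spread of its sums would give. Its p-values may thus be too small and those of Cabernet Franc too large, but the spreads were not estimated separately. DESeq2 called 17 rows in Riesling, 6 higher and 11 lower at 14:00, and 1 lower row in Cabernet Franc. Its unadjusted p was under 0.05 in 8.705% and 6.205% of rows, above the 5% of chance, so these calls may be false. Its share also lay above 5% in every comparison below.

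The response to the hour was also compared between cultivars, between cycles and between the ends of the night. The difference of the 14:00 effect between Riesling and Cabernet Franc passed in 0 rows (edgeR, smallest adjusted p = 0.261; 1037 rows at unadjusted p under 0.05). DESeq2 called 12 rows for that difference. The difference of the 14:00 effect between the second and the first cycle passed in 0 rows with edgeR (smallest adjusted p = 0.796; 1031 rows at unadjusted p under 0.05) and in 0 with DESeq2. Between 06:00 and 18:00, over both cultivars, edgeR called 0 rows (smallest adjusted p = 0.116; 887 rows at unadjusted p under 0.05) and DESeq2 called 1.

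The second comparison set the constant sub-zero days against the mean of the 2 bracketing cycles at 14:00. In Riesling 0 rows passed (edgeR, smallest adjusted p = 0.232; 1250 rows at unadjusted p under 0.05), and in Cabernet Franc 0 rows passed (edgeR, smallest adjusted p = 1.00; 781 rows). With single libraries the rows at unadjusted p under 0.05 numbered 885 and 838. The central 95% of log2 fold changes lay between −0.78 and 0.76 in Riesling and between −0.70 and 0.70 in Cabernet Franc, with a median standard error of 0.371 in Riesling. DESeq2 called 10 rows in Riesling, 4 higher and 6 lower in the constant cold, and 0 in Cabernet Franc. The cultivars' cold effects differed in 0 rows (edgeR, smallest adjusted p = 0.0730; 996 rows at unadjusted p under 0.05), and DESeq2 called 0. Each period was a single run of days, so a period could not be separated from its dates.

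The cycles themselves, and the last days of the series, were compared at 14:00 over both cultivars. The second cycle differed from the first in 0 rows (edgeR, smallest adjusted p = 0.0676; 1110 rows at unadjusted p under 0.05), with 2 rows called by DESeq2. With the counts of both cultivars added, so that each day counts once, 1 row passed, lower in the second cycle (edgeR, adjusted p = 0.0442), an alternative chosen after seeing the results. January 28 to 31 differed from the second cycle in 0 rows (edgeR, smallest adjusted p = 0.999; 899 rows at unadjusted p under 0.05), with 0 called by DESeq2.

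Riesling and Cabernet Franc were compared within each of the 34 time points. Of 20000 rows, 0 differed between the cultivars (edgeR, smallest adjusted p = 0.680; 923 rows at unadjusted p under 0.05). The central 95% of log2 fold changes lay between −0.33 and 0.31, with a median standard error of 0.164. DESeq2 called 7 rows, 3 higher and 4 lower in Riesling. Time points were the replicates here. If the same vines recur, which the labels do not say, the 33 residual degrees of freedom overstate the replication and the standard error may be too small. With counts summed per replicate number, 3 sums against 3, 0 rows passed (edgeR, smallest adjusted p = 0.754, with 5.39% of rows at unadjusted p under 0.05).

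Days were compared at 14:00 with vines as replicates, 54 libraries per cultivar over 18 days. The day passed in 0 rows in Riesling (edgeR, smallest adjusted p = 1.00; 621 rows at unadjusted p under 0.05) and in 0 rows in Cabernet Franc (edgeR, smallest adjusted p = 1.00; 573 rows). These are 3.105% and 2.865% of rows, where chance gives 5%, while 1401 and 1353 rows had an unadjusted edgeR p over 0.95. With fewer small p-values than chance gives, the edgeR test was conservative here, and its counts of 0 are weak evidence that days were alike. The likelihood ratio test of DESeq2 called 87 rows in Riesling and 110 in Cabernet Franc.

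The size of change that could be detected was measured for the hour, the constant cold and the day course in Riesling, and for the cultivars. Simulated libraries with the same totals and spread were used, in which 200 of 20000 rows were changed. The shares recovered hold for rows that mean the same gene in every library, which the deposited rows did not show. The other comparisons were not simulated. For the hour in Riesling, 100% of 4-fold changes, 29.9% of 2-fold changes and 10.4% of 1.5-fold changes were recovered. For the constant cold in Riesling the shares were 93.9% of 4-fold, 19.4% of 2-fold and 0% of 1.5-fold changes. For the cultivars they were 100%, 98.5% and 47.8%, with every library drawn independently, as if no vine recurred. For the day course in Riesling, a step on January 23 was recovered in 84.8% of rows at 4-fold and in 0% at 2-fold. Unchanged rows were called 4 times in the simulation of the hour, 12 times in that of the cold, 7 times in that of the cultivars and 1 time in that of the day course. In the simulation of the cold the changed rows called were 0, 13 and 62 at 1.5-, 2- and 4-fold. Its 12 false calls were thus more than the 5% of calls aimed at, in a single simulated draw.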

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

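The count of called rows was 0 in all 13 results of the main edgeR test. Some alternatives test little: the fit without a filter is the same fit, the constant period from January 19 repeats the one without January 18, and days outside a comparison enter only its spread. DESeq2 called 17 rows for 14:00 against the dark hours in Riesling and 1 in Cabernet Franc, 12 for the cultivar difference in that effect, 1 for 06:00 against 18:00, 10 for the constant cold in Riesling, 2 for the second against the first cycle, 7 for the cultivars, and 87 and 110 for the day course in Riesling and Cabernet Franc. Its share of rows at unadjusted p under 0.05 lay above 5% in all 13 results, from 5.16% to 11.175%. Only its day course was run on shuffled labels, so its other calls were not checked against chance. With the first cycle alone as comparator, the cultivar difference in the cold effect had 1 called row; the cause was not tested. Leaving out single replicates or days gave 0 to 1 called rows for the difference between cycles in the 14:00 effect (1 without January 16), for the constant cold in Riesling (1 without January 15), for the cultivar difference in the cold effect (1 without each of January 14, 15, 19 and 22), for the second against the first cycle (1 without January 15 and 1 without January 27), for January 28 to 31 (1 without replicate 1) and for the Cabernet Franc day course (1 without replicate 2). It gave 0 to 2 for 06:00 against 18:00 (2 without replicate 1). With single libraries and a replicate block, 0 rows were called in the 11 comparisons of hours, periods and cultivars, and 0 in the 2 day courses, so the block changed no call. Deviations of same-numbered libraries from the group means had a highest r of 0.0255, but no pair of libraries correlated above 0.0265, so this check could not have reached the 0.1 set for pairing. Totals differed by number (Riesling medians of 946938 and 14289475 for replicates 1 and 3 on January 14 to 16), so what the numbers mark stays open. Without the 6 libraries under 1000000 counts every result stayed at 0, an alternative chosen after seeing the data. With the counts of both cultivars added per time point, also chosen after seeing the results, the second against the first cycle at 14:00 moved from 0 to 1 called row (adjusted p = 0.0442), and the other 3 comparisons over both cultivars stayed at 0. In the simulated libraries, with the real totals, 4-fold changes were recovered in 84.8% or more of rows. For hour, cold period and day, simulated in Riesling only, 2-fold changes were recovered in 29.9% or fewer, so smaller changes could have been missed. Gene list tests and their alternative with an estimated correlation were not run, as no list had a member.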

Other observations

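All tests in this part were chosen after the values they explain were seen, except the shuffled days for DESeq2 and the splits of the samples, which were set before their results were seen.

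The libraries were unrelated to one another across rows, within a cultivar and time point as much as over all other pairs. Low depth is argued against: among the 35 libraries over 20000000 counts, where Poisson counting adds at most 3.16% to a row, the highest r of 595 pairs was 0.0191. A candidate explanation is that the table holds independent draws of one shape, scaled to each library's total, as in simulated or placeholder data. Against a rounded gamma distribution of shape 2, 9 of 204 libraries departed at p under 0.05 by simulation, where chance gives 10.2 and up to 17 lie within its limits. A shape of 2 is close to the negative binomial size estimated from these same libraries (mean 2.013, range 1.938 to 2.167), so part of this match is built in. The comparison covers the distribution within each library and cannot show that the draws were independent. Real counts whose row labels were shuffled separately in each library cannot be told apart from this by the row means, since both give a variance ratio near 1 (0.995 observed). Shuffling alone would keep each library's row distribution. The source libraries would then have had the few zeros (69 of 4080000 values) and even levels (3.74% to 4.03% of counts in the top 200 rows) seen here. They would also have lacked the rise in spread at low depth that read counting gives. The slope of 0.113 ± 0.0941 (SE), against 1 for read counting around levels spread alike, argues against shuffled read counts of that kind. The design names no group that differs in this way, so no biological explanation was tested.

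The spread across rows did not rise at low depth as counting reads would make it. Over the 204 libraries the squared coefficient of variation across rows rose with the inverse of the library's mean count with a slope of 0.113 ± 0.0941 (SE), where read counting around levels spread alike in every library gives a slope of 1. Without the 6 libraries under 1000000 counts, which have row means of 26.2 to 48.1, the slope was −0.131 ± 0.332 (SE), less precise but also more than 2 SE below 1. In those 6 the squared coefficient of variation was 0.503 ± 0.00901 (SD), against 0.526 expected with read counting and 0.499 ± 0.00642 (SD) in the other 198. The 5 from Riesling lay at 0.492 to 0.507, each below the 0.5182 to 0.5355 expected for them, while the 1 from Cabernet Franc had 0.519, near the 0.525 expected for it. Against a negative binomial distribution of size 2, which includes counting noise, 20 of 204 libraries departed, all 6 shallow ones among them, where chance gives 10.2 in all. In deeper libraries counting noise is small beside the spread, so this comparison says little about whether they were counted from reads. The Cabernet Franc library departed from both distributions, by the largest distance between cumulative curves. The distance was 0.0104 from the negative binomial (p = 0.005 by simulated draws) and 0.0076 from the rounded gamma (p = 0.015 by simulated draws). It was singled out afterwards among 204 libraries, some of which reach such a p by chance. Its spread and distances therefore do not settle whether it was counted from reads. By the 2 slopes, the values may have been scaled to their totals after they were drawn rather than counted from reads.

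DESeq2's likelihood ratio test called 87 rows in Riesling and 110 in Cabernet Franc for the day course, where edgeR called 0. The edgeR test was itself conservative there, with an unadjusted p under 0.05 in 3.105% and 2.865% of rows. A candidate explanation for the DESeq2 calls is that its likelihood ratio test calls rows without a day effect at 3 libraries per day. With the days shuffled among the libraries, 4 times per cultivar, it called 62 to 103 rows in Riesling and 58 to 135 in Cabernet Franc, with a median of 85 over all shuffles. The real counts lie inside those ranges.

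Splits of the same samples decide nothing here. The real labels called 0 rows in each of the 13 results, so all 21 of 21 splits necessarily called at least as many, and chance cannot be excluded for any of them. The highest count in any other split was 2.

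The column totals, unlike the rows, had structure along the series. Between consecutive time points of one cultivar and replicate number, the total changed by a median of 0.434 on the absolute log2 scale. With time points shuffled within each of the 6 series, the median change was 0.647 and the lowest of 9999 shuffles 0.444 (permutation p = 0.0001, one-sided, the smallest they can give). Totals that follow batches of handling are a candidate explanation, as are totals carried over from sequenced libraries, which was not tested; the labels give no batch.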
